A study of Arabidopsis thaliana with 6 samples.

How the data were processed

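The samples were inflorescence apices of Arabidopsis thaliana of the Landsberg erecta accession, in 2 groups of 3 libraries each. The RGA-GFP plants expressed a form of RGA that gibberellin does not remove, fused to green fluorescent protein (GFP) and driven by the RGA promoter. The wild type plants carried no GFP and served as the control without the epitope. Per the labels, each group had 3 biological replicates, and chromatin was fixed with formaldehyde and a second crosslinker, precipitated with anti-GFP beads and sequenced as single-end reads. Samples were grouped by their titles, which also number the replicates. The labels do not say that a number marks a shared day or batch.

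Per the submitters' processing notes, Bowtie2 and SAMtools were used, reads were placed on the TAIR10 build, and peaks were called with MACS2 2.0.10; the file headers give MACS 2.0.10.20130915. Per the file headers, each library was called by itself with no control, with tags extended to 300 bp, a q cutoff of 0.05, an effective genome size of 90 Mb, 1 tag kept per position and a local background taken from 10000 bp. Per the file headers, a pooled list was called from the combined RGA-GFP replicates against the combined wild type replicates, with a local background from 1000 and 10000 bp. The fold enrichment of each peak is the authors' ratio of the summit pileup to the local background: the library's own background in the single lists, and that of the combined wild type in the pooled list. A fold in a single list and a fold in the pooled list are therefore different ratios. The significance of each peak is the authors' −log10 of the MACS q value. The pileup is the authors' signal at the summit, the number of extended tags that cover it after duplicates were removed. Each of the 7 peak lists came as a pair of deposited files, and both files of each pair held the same peaks.

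The authors' deposited table of genes gives, per the file headers, the number of RGA-GFP replicate lists (1 to 3) with a peak in the window of a gene, and the fold and −log10 q of the pooled list, with 0 where the window has no pooled peak. Per the file headers, windows run from 3000 bp upstream to 1500 bp downstream of the coding sequence, an overlap takes at least 50 bp, and replicate peaks needed a log10 q of 3. Of the windows' edges, 26.0% lay on the edge of an annotated gene, against 1.12% when the windows were shifted, so some windows end at the edge of a neighbouring gene. Recomputing the fold from the pooled list gave the value of the table for 98.2% of genes.

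The comparisons, tests, gene lists, thresholds, the rule for named genes and most of the alternatives were fixed before the data were examined. The rule from peak to gene had been written for an annotation with strand. The gene table used here (RefSeq assembly GCF_000001735.4, TAIR10.1) has no strand and no exons, so the authors' table, which had been fixed as an alternative, became the main rule: a protein-coding gene has a pooled peak where that table lists it with a pooled fold above 0. The table held 13426 genes, of which 13259 (98.8%) matched a RefSeq gene. RefSeq coordinates served only to place summits relative to genes, to find neighbours and to estimate window lengths, and none is printed. Gene direction was read from the authors' windows where only 1 flank was longer than the downstream limit, which gave a direction for 1882 genes. Classes of exon, intron and untranslated region, sequence motifs, and windows that need strand were not analysed here.

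Peak lists were compared by an overlap of at least 1 bp. Chance levels came from 100 shuffles of the peaks within chromosomes, or from 100 sets of random positions. Counts of peaks per library were compared by an exact permutation test, two-sided, for which the smallest p with 3 against 3 is 0.1. The 22 gene lists (273 genes, each a RefSeq gene) were tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 22 lists, and a list passed at an adjusted p under 0.05. A further test compared each list with 10000 random lists matched on estimated window length in 10 bins. The estimate was the RefSeq gene length plus the gap to the neighbouring gene on each side, up to a limit. It took no account of strand and is not the length of the authors' window. A separate Fisher's exact test, two-sided, compared the members with a pooled peak with all other genes with a pooled peak, for a wild type peak in the window, also adjusted over the 22 lists. A one-sided test, chosen after seeing the data, compared the members' peaks with pooled peaks of like fold (20 bins, 10000 draws) for overlap with wild type library 1 or 3. It took the strongest pooled peak of each member, and only peaks found in all 3 RGA-GFP lists, matched on the mean replicate fold. It counts direct overlap with the peak, not a wild type peak elsewhere in the window. The lists covered DELLA genes, gibberellin biosynthesis, inactivation and perception, INDETERMINATE DOMAIN genes, DELLA partners of the bHLH and BZR families, cell cycle inhibitors and drivers, shoot meristem, floral and organ polarity genes, auxin, cytokinin, brassinosteroid and jasmonate genes, TCP and SPL genes, the circadian clock, markers of anthers, vascular tissue and roots, and seed storage and photosynthesis genes as control lists. Intervals on shares are exact binomial (Clopper-Pearson) 95% intervals and cover counting error only.

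Genes were named by a fixed rule: the genes at the 10 pooled peaks of highest −log10 q among those found in all 3 RGA-GFP lists and no wild type list; in each gene list up to 4 members of highest −log10 q, with every member of the DELLA, gibberellin and cell cycle inhibitor lists and any member without a peak free to be named; the genes at the 5 strongest pooled peaks that overlap a wild type peak; and RGA itself. Genes outside this rule are said to be so.

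The depth after duplicate removal was 14644122, 15704296 and 16745139 tags in the RGA-GFP libraries and 10014730, 8808462 and 3999159 in the wild type libraries. A shallower library gives fewer peaks at the same enrichment, so the wild type lists can miss weak background. The alternatives were stricter q and fold thresholds, other definitions of overlap, other distances to genes, leaving out each replicate in turn, the replicate number as a block, the matched random lists, and others chosen after seeing the data.

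The steps were tested on simulated data. For 40 simulated families of the 22 lists over 27444 genes, with members given a peak at 75% in enriched lists and at 30% elsewhere, Fisher's exact test called 70.9% of the enriched lists (85.8% of those with 14 members or more) and 0.682% of the others. In lists of long windows with no other enrichment, 17.2% had a p under 0.05 by Fisher's exact test and 2.73% by the matched lists. The simulated peaks followed the same estimate of window length, so the estimate itself was not tested. The overlap step gave the right answer for 100% of 6000 simulated peaks. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with the random seed 20170217.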

Results

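Chromatin immunoprecipitation and sequencing (ChIP-seq) was used to locate RGA on the genome in inflorescence apices of Arabidopsis thaliana. RGA is a DELLA protein, one of the nuclear repressors of gibberellin responses that the hormone removes. The RGA-GFP plants expressed a GFP fusion that gibberellin does not remove, and wild type plants without GFP gave the background of the same pull-down. Each group had 3 biological replicates. The RGA-GFP libraries held 14644122, 15704296 and 16745139 tags after duplicates were removed, and the wild type libraries 10014730, 8808462 and 3999159. Peak positions, fold enrichments and q values are those of the authors' peak lists, and coordinates are those of the TAIR10 build.

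RGA-GFP gave peaks at all 5 DELLA genes, at genes of gibberellin perception, at every listed inhibitor of the cell cycle, and at regulators of flower, organ and shoot apex development. It also gave them at most genes of photosynthesis, a control list that had the lowest p of all lists. The RGA-GFP lists held 10636, 11116 and 9343 peaks (mean 10365 ± 917, SD, n = 3), and the wild type lists 972, 285 and 527 (mean 595 ± 348, SD, n = 3). The ratio of the means was 17.4 and every RGA-GFP library lay above every wild type library (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). RGA-GFP libraries were also deeper, with 2.06 times the tags kept (ratio of the means, exact permutation test, two-sided, p = 0.1). Relative to the tags kept, peaks were still 7.63 times as many in RGA-GFP as in wild type (ratio of the means, exact permutation test, two-sided, p = 0.1). Duplicates took 63.4% and 62.1% of the tags of wild type libraries 1 and 3, and 34.9% of those of library 2, against 39.8%, 32.4% and 39.6% in the RGA-GFP libraries.

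**Figure D1:**
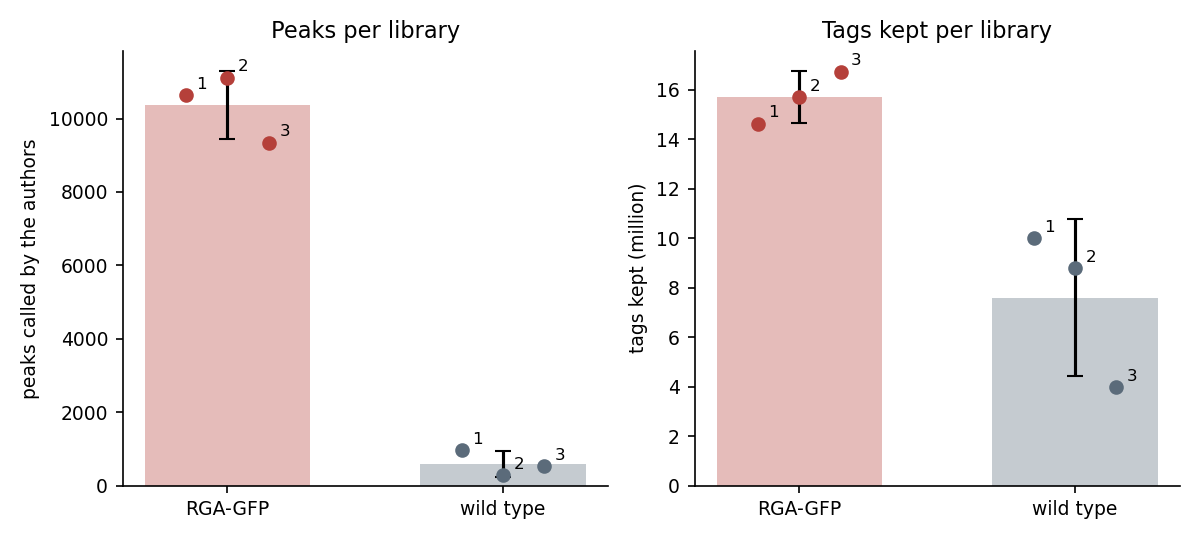
Number of peaks (left) and tags kept after duplicate removal (right) in each library; points are the numbered replicates, bars the mean and error lines the SD (n = 3 per group). Every RGA-GFP library had more peaks than every wild type library (9343 or more against 972 or fewer), and also more tags (14644122 or more against 10014730 or fewer).

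The authors' pooled list held 8112 peaks covering 4.70 Mb, with a median length of 479 bp. The median fold over the combined wild type was 1.70 (quartiles 1.57 and 1.87), the highest was 3.54, and 1168 peaks reached 2. Of the pooled peaks, 6281 (77.4%) overlapped a peak in all 3 RGA-GFP lists, against 7.15% of shuffled peaks, and 413 (5.09%) overlapped none. The share found in a single replicate was 88.4%, 90.5% and 83.0% (mean 87.3% ± 3.90, SD, n = 3), although pooled and single lists share reads. Between replicates, 71.6%, 68.6% and 82.5% of the peaks of a list were found in both others, against 8.01%, 7.76% and 8.81% after shuffling. Across the 6281 peaks, which are not independent replicates, Spearman's rho of the fold between replicates was 0.881, 0.826 and 0.846.

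A pooled peak was assigned to 8156 of 27444 protein-coding genes (29.7%, exact 95% interval 29.2 to 30.3) in the authors' deposited table. A peak could count for more than 1 gene: 51.7% of assigned peaks lay in the windows of at least 2 genes. Of the 22 gene lists, 15 had more members with a pooled peak than other genes had (Fisher's exact test, two-sided, adjusted p under 0.05), and no list passed with fewer. Each p marked Fisher on members with a pooled peak is from this test, and each on wild type peaks is from the same test among genes with a pooled peak, both adjusted over the 22 lists. Against random lists matched on estimated window length, 12 of the 15 passed. By share alone, 21 of the 22 lists lay above other genes, and 21 above the mean of their matched lists. Root markers were the exception in both, so a raised share was common to nearly all lists chosen.

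**Figure D2:**
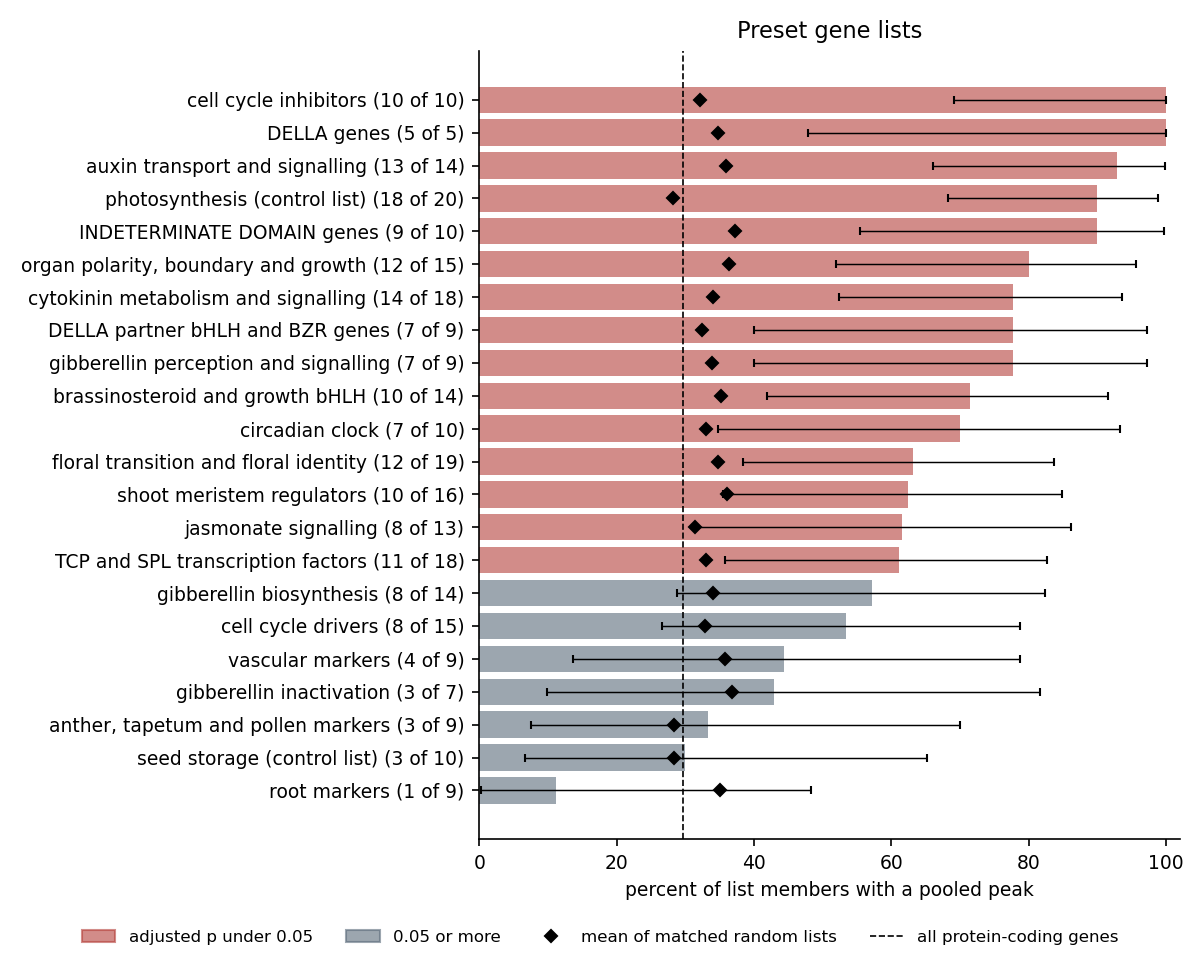
Percent of the members of each preset gene list that had a pooled peak (bars, with exact 95% binomial intervals). Bars are red where the adjusted p of Fisher's exact test was under 0.05. Diamonds mark the mean of 10000 random lists matched on estimated window length, and the dashed line all protein-coding genes (29.7%). Cell cycle inhibitors and DELLA genes stood at 100% and root markers were lowest, at 11.1%.

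The DELLA genes all had a pooled peak, 5 of 5 against 29.7% of other genes (Fisher adjusted p = 0.00637). At GAI (AT1G14920), the closest relative of RGA, the peak lay 912 bp upstream of the gene (chromosome 1, 5147832 to 5148357), with a pooled fold of 1.82 and 2.71 ± 0.45 in the replicate lists (SD, n = 3). The peak at RGL2 (AT3G03450), the DELLA gene that restrains germination, had a pooled fold of 2.01 (chromosome 3, 818955 to 819600, and 1.85 ± 0.10 in the replicate lists, SD, n = 3). RGL3 and RGL1 had peaks inside the gene, with pooled folds of 1.83 and 1.63. RGA itself is described with its locus, since its sequence is also in the transgene, and it was the 1 member of the list with a wild type peak in its window.

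Gibberellin perception and signalling genes had peaks at 7 of 9 members (Fisher adjusted p = 0.00808). These were the 3 receptors GID1A, GID1B and GID1C; SLY1, the F-box gene through which DELLA proteins are degraded; SCL3, a GRAS gene that counteracts DELLA proteins; SEC, whose product glycosylates them; and XERICO, a RING finger gene. The strongest lay inside SCL3 (AT1G50420, chromosome 1, 18679755 to 18680414), with a pooled fold of 2.91 and 3.08 ± 0.44 in the replicate lists (SD, n = 3), and a separate peak in the SCL3 window overlapped wild type peaks. GID1B (AT3G63010) had its peak 346 bp downstream (chromosome 3, 23291285 to 23292070; pooled fold 2.79, and 2.25 ± 0.19 in the replicate lists, SD, n = 3) and GID1A (AT3G05120) 1593 bp upstream (chromosome 3, 1428505 to 1429945; pooled fold 2.40, and 3.54 ± 0.42 in the replicate lists, SD, n = 3). SNE and SPY had none.

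Gibberellin biosynthesis genes had peaks at 8 of 14 members, which did not pass (Fisher adjusted p = 0.0507). Among the 20-oxidases, which catalyse late steps of the pathway, GA20OX2 (AT5G51810) had a pooled fold of 2.68 at a site 413 bp downstream (chromosome 5, 21054497 to 21055006, and 3.90 ± 0.56 in the replicate lists, SD, n = 3), GA20OX3 2.36 and GA20OX1 1.81. GA2, KAO2, GA3OX1, GA3OX2 and, by the authors' deposited table alone, GA3OX4 made up the rest, while GA1, GA3, KAO1, GA20OX4, GA20OX5 and GA3OX3 had no peak. None of the 8 had a wild type peak in its window. The 2-oxidases, which inactivate gibberellin, had peaks at 3 of 7 members (Fisher adjusted p = 0.499), the strongest 2690 bp upstream of GA2OX1 (AT1G78440, chromosome 1, 29515570 to 29516054; pooled fold 2.45, and 3.66 ± 0.48 in the replicate lists, SD, n = 3).

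INDETERMINATE DOMAIN genes encode zinc finger proteins through which DELLA proteins contact DNA, and 9 of 10 had a peak (Fisher adjusted p = 0.000484), all but NUC. The strongest was 2808 bp upstream of JKD (AT5G03150, chromosome 5, 742225 to 742923; pooled fold 2.64, and 3.92 ± 0.36 in the replicate lists, SD, n = 3), followed by IDD1, IDD9 and IDD4 with pooled folds of 2.31, 2.40 and 2.17. At IDD1 the peak overlapped peaks of 2 wild type lists. The call of this list was lost under 1 of 12 alternatives, the summit in the gene (range of the adjusted p 2.82e-06 to 0.0538). The genes of DELLA partners had peaks at 7 of 9 members (Fisher adjusted p = 0.00808), among them the phytochrome-interacting factors PIF4 (pooled fold 2.25), PIF5 (2.09) and PIF7 (1.86) and the carpel gene SPT (1.86), and not at BZR1 or ALC. PIF4, PIF5 and PIF7 each overlapped a peak of 1 wild type list, and 3 of the 7 had a wild type peak in their window against 9.80% of other genes with a pooled peak (Fisher adjusted p = 0.108). Counting only pooled peaks found in replicates 2 and 3, with replicate 1 left out, left 5 of 9 partners (55.6%, Fisher adjusted p = 0.0976), and with replicate 2 left out also 5 (Fisher adjusted p = 0.0905; range over the alternatives 0.00714 to 0.563).

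The cell cycle inhibitors had a pooled peak at 10 of 10 members (Fisher adjusted p = 3.93e-05). They comprise KRP genes, which encode inhibitors of cyclin-dependent kinases, and the related SIM and SMR genes. At KRP2 (AT3G50630) the peak lay 1030 bp downstream (chromosome 3, 18802277 to 18802891; pooled fold 2.46, and 3.01 ± 0.39 in the replicate lists, SD, n = 3). At KRP1 (AT2G23430) and KRP4 (AT2G32710) it lay inside the gene, with pooled folds of 1.99 and 2.04 and 4.26 ± 0.42 and 3.79 ± 0.42 in the replicate lists (SD, n = 3). SMR2, KRP3, KRP5, KRP7, SIM, KRP6 and SMR1 had pooled folds of 1.88, 1.78, 1.76, 1.70, 1.64, 1.58 and 1.42. By the authors' deposited table, SIM and SMR1 each had a peak in only 2 RGA-GFP replicate lists. Counting only pooled peaks with a −log10 q of at least 10 left 4 of 10 inhibitors (40%, Fisher adjusted p = 0.0218). Wild type peaks lay in the windows of KRP4 and KRP6. Cell cycle drivers had peaks at 8 of 15 members (Fisher adjusted p = 0.109), among them the D-type cyclins CYCD3;1 (pooled fold 2.22) and CYCD3;2 (1.74), the kinase CDKA;1 (1.84) and RBR1 (1.88), a retinoblastoma gene that was set in this list although it restrains entry into the cycle. Of these 8, 4 had a wild type peak in the window, against 9.79% of other genes with a pooled peak (Fisher adjusted p = 0.0345). Against pooled peaks of like fold there was no call (2 of 6 distinct peaks, permutation by random draws, one-sided, adjusted p = 0.300). That test took only peaks found in all 3 RGA-GFP lists and direct overlap with wild type library 1 or 3. It therefore differs from the window count by more than fold.

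Floral genes had peaks at 12 of 19 members (Fisher adjusted p = 0.00808). The strongest lay 1709 bp upstream of AP2 (AT4G36920), a floral organ identity gene (chromosome 4, 17398439 to 17399215; pooled fold 2.74, and 3.38 ± 0.28 in the replicate lists, SD, n = 3), followed by the MADS-box genes FUL (2.36), SVP (2.43) and AP3 (2.02). CAL, AG, AGL24, TFL1, UFO and SUP had none. PI counts as a member without one because the authors' deposited table gives it a fold of 0, although the pooled list has a peak inside the gene (chromosome 5, 6828839 to 6829237, fold 1.65) that overlaps no replicate peak. Of the 12, 5 had a wild type peak in the window (41.7% against 9.79%, Fisher adjusted p = 0.0345), AP2 and AP3 among them. Against pooled peaks of like fold there was no excess (2 of 11 distinct peaks, 2.23 on average in the draws, permutation by random draws, one-sided, adjusted p = 1). As for the cell cycle drivers, the fold-matched test took only peaks found in all 3 RGA-GFP lists and direct overlap with library 1 or 3. It therefore differs from the window count by more than fold. The call of the floral list was lost under 3 of 12 alternatives (range of the adjusted p 0.00154 to 0.0637). Shoot meristem regulators had peaks at 10 of 16 members (Fisher adjusted p = 0.0159, and 0.0812 against matched lists). ATH1 (AT4G32980), a BELL homeobox gene, had a peak 67 bp upstream (chromosome 4, 15918005 to 15918799; pooled fold 2.76, and 4.74 ± 0.86 in the replicate lists, SD, n = 3), and the KNOX genes KNAT2 and KNAT6 had pooled folds of 2.28 and 1.95. CLV1, a receptor kinase that limits the stem cell niche, had 2.07 and overlapped a peak of 1 wild type list, while WUS, CLV2, CLV3, KNAT1, CUC2 and LAS had no pooled peak. With replicate 1 or replicate 2 left out, and peaks required in both others, 7 of 16 regulators remained (43.8%, Fisher adjusted p = 0.211 and 0.218; range over the alternatives 0.00772 to 0.378). Genes of organ polarity, boundaries and growth had peaks at 12 of 15 members (Fisher adjusted p = 0.000362), with BOP1 (2.46), PTL (2.45), AIL6 (2.37) and BOP2 (2.28) strongest, and none of the 12 had a wild type peak. With the summit in the gene this call was lost (20%, Fisher adjusted p = 0.552, range over the alternatives 0.000259 to 0.552).

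Among hormone genes, auxin transport and signalling had peaks at 13 of 14 members (Fisher adjusted p = 1.56e-05). The auxin biosynthesis gene YUC4 (AT5G11320) had a peak 2374 bp upstream (chromosome 5, 3615770 to 3616310; pooled fold 2.60, and 3.77 ± 0.62 in the replicate lists, SD, n = 3), and the kinase gene PID, the Aux/IAA gene SHY2 and the auxin response factor ETT had pooled folds of 2.22, 2.21 and 1.97. Cytokinin genes had peaks at 14 of 18 members (Fisher adjusted p = 0.000192), among them the response regulator ARR7 (2.00), the receptors AHK4 and AHK3 (1.97 each) and the oxidase CKX5 (1.85), whose peak overlapped a peak of 1 wild type list. This call was lost under 3 of 12 alternatives (range of the adjusted p 9.40e-05 to 0.104). Brassinosteroid and growth bHLH genes had peaks at 10 of 14 (Fisher adjusted p = 0.00482), led by the receptor BRI1 (AT4G39400, 1665 bp upstream, chromosome 4, 18322354 to 18323833; pooled fold 2.24, and 3.68 ± 0.27 in the replicate lists, SD, n = 3), then ROT3 (1.89), KDR (1.95) and HBI1 (1.95). The peak at ROT3 overlapped peaks of 2 wild type lists, and the call of the list was lost under 5 of 12 alternatives (range of the adjusted p 0.00382 to 0.106).

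Jasmonate signalling genes had peaks at 8 of 13 members (Fisher adjusted p = 0.0401, and 0.0704 against matched lists). The repressor genes JAZ3, JAZ6, JAZ1 and JAZ10 led, with pooled folds of 2.11, 1.54, 1.59 and 1.57; at JAZ6 (AT1G72450) the replicate lists gave 4.17 ± 0.29 (SD, n = 3) at a site 310 bp upstream (chromosome 1, 27276674 to 27277077). Wild type peaks lay in the windows of 7 of the 8 (87.5% against 9.76% of other genes with a pooled peak; Fisher adjusted p = 1.40e-05), all but JAZ12, a gene named here after its values were seen. With pooled peaks that overlap a wild type peak left out, 2 of 13 members kept a peak, 15.4% against 28.2% of other genes (Fisher adjusted p = 0.474; range over the alternatives 0.00714 to 1). TCP and SPL genes had peaks at 11 of 18 (Fisher adjusted p = 0.0135), with SPL10 and SPL11 sharing a peak (2.1) and TCP14 (2.14) and TCP4 (1.87) next, and 4 of the 11 had a wild type peak in the window (Fisher adjusted p = 0.0958). Clock genes had peaks at 7 of 10 (Fisher adjusted p = 0.0159, and 0.0569 against matched lists), led by PRR5 (1.83), TOC1 (1.94), CCA1 (1.80) and PRR9 (1.78); PRR5 and CCA1 each overlapped a peak of 1 wild type list. Under 12 alternatives the clock call was lost in 5, and in 1 more, with the summit in the gene, the share fell below that of other genes (10% against 12.8%, range of the Fisher adjusted p 0.00903 to 1).

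Marker lists of other tissues did not pass: anther, tapetum and pollen 3 of 9 (SPL, MS1 and A9; Fisher adjusted p = 0.765), vascular 4 of 9 (SMXL5, PXY, TMO6 and HB8; Fisher adjusted p = 0.511) and root 1 of 9 (SCR; Fisher adjusted p = 0.362). Seed storage genes, a control list, had peaks at 3 of 10 (SESA1, CRA1 and CRU2; Fisher adjusted p = 1). Photosynthesis genes, the other control list, had peaks at 18 of 20 members, 90% against 29.7% of other genes (Fisher adjusted p = 6.97e-07). Matched lists held 5.65 such genes on average (permutation by random draws, two-sided, adjusted p = 0.0022). The light-harvesting genes LHCA2 (2.08), LHCA4 (2.12), LHCB1.4 and LHCB1.5 (2.07, a shared peak) were strongest, and 2 of the 18 had a wild type peak in the window, against 9.83% of other genes with a pooled peak (Fisher adjusted p = 1).

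The 10 strongest pooled peaks found in all 3 RGA-GFP lists and no wild type list lay at genes outside the preset lists. The highest was 1543 bp from PGM (AT5G51820), which encodes the plastid phosphoglucomutase of starch synthesis (chromosome 5, 21061368 to 21062814), with a −log10 q of 60.0, a pooled fold of 3.54 and 5.08 ± 0.34 in the replicate lists (SD, n = 3). Next came a site 1041 bp upstream of MEE3 (AT2G21650), a small MYB-like gene also called RSM1 (chromosome 2, 9258126 to 9258892; pooled fold 3.52, and 5.44 ± 0.85 in the replicate lists, SD, n = 3), and one 1990 bp upstream of AT2G28390 (MON1), a vesicle traffic gene (chromosome 2, 12145280 to 12146070; pooled fold 3.34, and 5.59 ± 1.12 in the replicate lists, SD, n = 3). Others lay at AT4G05080, AT4G04630, the glutathione transferase GSTU9, AT4G19700, the threonine aldolase THA1 and the mannan synthase gene CSLA01, with pooled folds from 2.75 to 3.38. AT4G19700 encodes BOI, a RING protein that binds DELLA proteins; its peak lay 2613 bp upstream (chromosome 4, 10717047 to 10717747; pooled fold 2.96, and 3.09 ± 0.38 in the replicate lists, SD, n = 3). AT4G05080, 2100 bp from its peak, is not listed in the authors' deposited table.

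At RGA (AT2G01570) the window held 4 pooled peaks, and only the farthest upstream was also found in wild type. Those at 254066 to 254381 and 258044 to 258537 overlapped no peak of any RGA-GFP replicate list. A peak over the gene body (chromosome 2, 255456 to 257519) had a pooled fold of 2.45, and in the replicate lists the gene body peaks had folds from 1.49 to 1.84. The upstream peak (chromosome 2, 258703 to 261019), with its summit 1554 bp from the gene, had a pooled fold of 2.17 and 3.35 ± 0.08 in the replicate lists (SD, n = 3). Wild type library 1 had a peak there with a fold of 2.90 (258894 to 259396) and library 3 one with 2.92 (258969 to 259360), each over its own local background, and library 2 had none. No wild type list had a peak over the gene body, where the transgene adds copies of the coding sequence. The transgene is driven by the RGA promoter, so it can add copies of upstream sequence too.

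**Figure D3:**
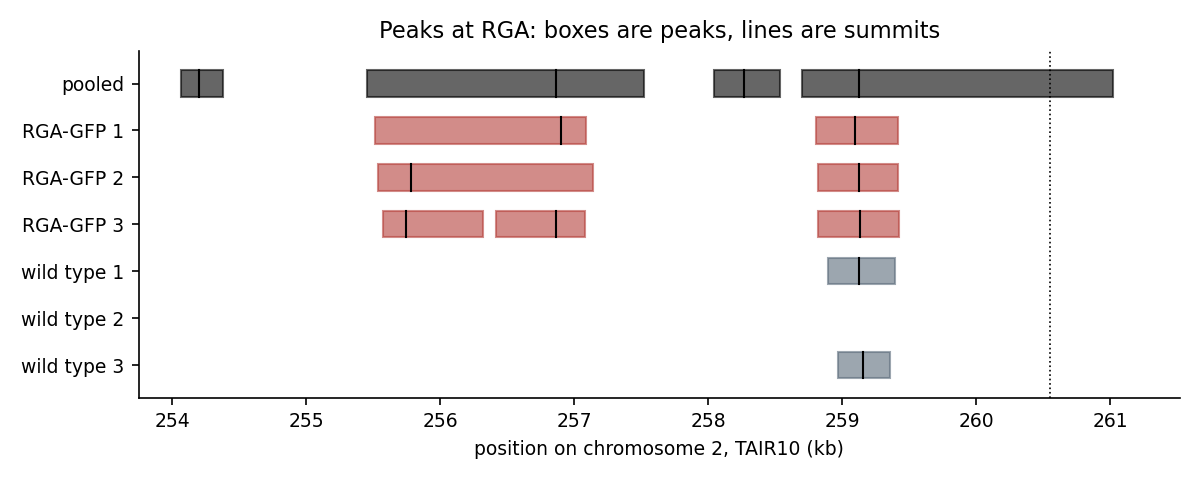
Peaks (boxes) and summits (lines) in the authors' window of RGA on chromosome 2, in kb of the TAIR10 build, for the pooled list and the 6 libraries; the dotted line marks the right edge of the window. The gene body peak, from 255456 to 257519 in the pooled list, has no counterpart in wild type, while the peak that starts at 258703 in the pooled list appears in wild type libraries 1 and 3.

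Of the peaks of wild type libraries 1, 2 and 3, 79.3%, 64.9% and 70.8% overlapped a peak in all 3 RGA-GFP lists, which were called without a control. Only 46.9%, 9.82% and 28.5% overlapped a pooled peak, a site enriched over wild type. In the other direction 510 pooled peaks (6.29%) overlapped a wild type peak, against 84.1 (1.04%) after shuffling. Library 1 gave 456 of these overlaps, library 3 151 and library 2 28, and without library 1 the share fell to 2.02%. The 5 strongest such peaks lay at LCR32 (AT2G28405, a defensin-like gene; pooled fold 2.57), 3623 bp upstream of the ERF-family gene AT1G64380 and outside its window (2.37), between SCL3 and the sterol reductase gene DWF5 (chromosome 1, 18680659 to 18681716; 2.29, and 5.10 ± 0.62 in the RGA-GFP lists, SD, n = 3), at the receptor-like kinase gene AT5G67280 (2.35) and upstream of RGA. Of the 8156 genes with a pooled peak, 802 (9.83%) had a wild type peak in the window.

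Pooled peaks gathered beside genes, relative to random positions. These positions were drawn over whole chromosomes, whether or not reads could be placed there, so part of the difference can come from such stretches. A summit lay within a protein-coding gene for 48.4% of peaks (exact 95% interval 47.3 to 49.5; random positions 54.1%), within 1000 bp of one for 36.9% (35.8 to 37.9; random 20.4%), and farther away for 14.7% (random 25.5%). Among the 2000 peaks with a −log10 q of at least 10, these shares were 34.1%, 43.8% and 22.2%. Summits of wild type libraries 1, 2 and 3 lay within 1000 bp of a gene in 33.1%, 18.2% and 33.2% of cases (random 20.4%, 20.2% and 20.8%). A raised share beside genes was therefore also seen without the epitope, in libraries 1 and 3. Wild type summits lay farther than 1000 bp from a gene in 31.3%, 60.7% and 40.2% of cases. In the 1882 genes of known direction, 356 summits lay within 1000 bp upstream, 703 inside the gene and 344 within 1000 bp downstream. Genes with an upstream summit alone (271) and those with a downstream summit alone (261) were nearly equal in number (exact McNemar test, two-sided, p = 0.696). Direction could be read only for genes with a long free flank upstream, and genes with a flank under 1000 bp were left out. The sides therefore differ in how close a neighbouring gene can lie, and near-equal numbers do not show that RGA-GFP lacked a preference. All 1882 genes had an RGA-GFP replicate peak in the window, so these counts and densities do not describe genes in general. Density was highest just around the start: 308 and 298 summits per kb per 1000 genes in the last 2 bins of 100 bp before the gene, and 344 and 277 in its first 2 of 20 bins.

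**Figure D4:**
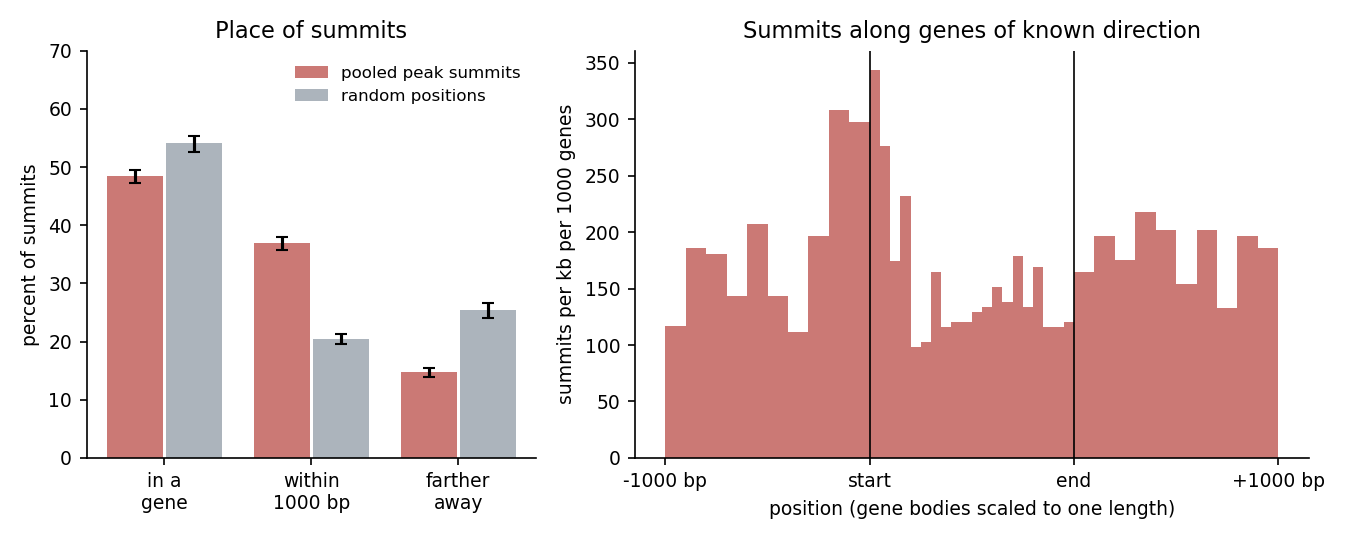
Left: percent of pooled summits inside a protein-coding gene, within 1000 bp of one and farther away (red, exact 95% binomial intervals), beside 100 sets of random positions (grey, lowest and highest set). Right: summits per kb per 1000 genes along 1882 genes of known direction, all with an RGA-GFP replicate peak in the window. Gene bodies are scaled to 1 length. The highest bin, 344, is the first in the gene.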

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

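All tests in this part, with their bounds, were chosen after the results they bear on had been seen. They were also revised: 8 tests were first written, 6 of them stand as first written, 2 were replaced or reworded after their outcomes were seen, and 1 was added for the same reason, so that 9 are reported. The added one is the fold-matched test of jasmonate genes, run because the test of a fixed share of reads had left the question open. The replaced one asked how many photosynthesis genes with a peak had no wild type peak in the window (16 of 18, 88.9%, past its bound of 80%), which depends on the depth of the wild type libraries. The reworded one first spoke of signal at transcribed genes that needs GFP, until the wild type ratio was seen; its value and bounds did not change.

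Genes of tRNA, snoRNA and snRNA, which none of the comparisons used, are given here because RGA-GFP peaks lay at them at more than 2 times the shuffled share. Their share also exceeded that of every wild type list, which the longer RGA-GFP lists would give by themselves, so the ratio to shuffled peaks of the same list is what can be compared. Of 625 tRNA genes, 43.4% ± 4.55 (SD, n = 3 lists) had an RGA-GFP peak within 200 bp, against 9.38% after shuffling, a ratio of 4.63. In wild type it was 2.03% ± 1.49 (SD, n = 3) against 0.485%, a ratio of 4.18, with 23, 5 and 10 genes in libraries 1, 2 and 3. Of 287 snoRNA genes it was 26.0% ± 5.68 (SD, n = 3) against 9.56%, a ratio of 2.72, and wild type peaks lay at 0, 0 and 1 of them. Of 82 snRNA genes it was 41.5% ± 2.44 (SD, n = 3) against 10.1%, a ratio of 4.1, and wild type peaks lay at 9, 0 and 0 of them, too few and too uneven for a ratio. These RGA-GFP lists were called without a control. In the pooled list, called against wild type, tRNA genes stood at 23.7% against 6.91% after shuffling. There snoRNA genes stood at 11.8% against 7.30%, less than 2 times the shuffled share, and snRNA genes at 29.3% against 7.68%.

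Photosynthesis genes had peaks at 18 of 20 members although the list was set as a control. Called wild type peaks do not account for this. With pooled peaks that overlap one left out, the adjusted p was 2.89e-07 (Fisher's exact test). Only 2 of the 18 members had a wild type peak in the window, so leaving these out could change little. Like the test it replaced, this depends on the depth of the wild type libraries. Wild type peaks too weak to be called stay in, so pull-down without the epitope stays open. Called ones lay within 1000 bp of 10% of members and 3.75% of all genes. List members that share a peak with each other do not account for the 18 members, since these held 16 distinct peaks. Whether those peaks also lay in the windows of genes outside the list was not tested. Of all assigned peaks, 51.7% lay in the windows of at least 2 genes, so assignment from such neighbours stays open. Signal at strongly transcribed genes of any kind stays open. The tRNA genes carried RGA-GFP peaks at 4.63 times the shuffled share. They were brought in because that ratio exceeded 2, which was also the bound of the test, so the outcome was built in. Wild type peaks lay at tRNA genes at 4.18 times their shuffled share, so part of the tRNA signal may not need GFP. At protein-coding genes the ratio was 0.838 in wild type and 1.33 in RGA-GFP, so this cannot be carried over to photosynthesis genes. A role of RGA at photosynthesis genes is equally open and was not tested, since no expression data were used here.

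Wild type peaks at RGA-GFP sites have several possible sources. Depth stays open: library 1, with the most tags, had the most overlaps with pooled peaks (456), but library 3, with fewer tags than library 2, had 5.39 times as many as library 2, and single libraries give no spread. A fixed share of RGA-GFP reads in libraries 1 and 3 would mark the strongest sites most, and 63.6% of 33 sites with a mean fold of at least 5 had such a peak (exact 95% interval 45.1 to 79.6) against 5.25% of 5653 sites under 3, which neither meets nor excludes it; for jasmonate genes it is argued against, since 7 of 8 distinct peaks overlapped a peak of these libraries while fold-matched draws gave at most 4 (central 95%; mean 1.73; one-sided p = 0.0001, the smallest 10000 draws can give; adjusted over 22 lists 0.0022). Pull-down without the epitope that is alike in every wild type library cannot be told apart from one that differs, with 18.0% of the 477 peaks of library 1 at such sites found in library 2 and 32.3% in library 3. No biological explanation was tested.

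At RGA and in other broad stretches the pooled fold exceeded the mean fold of the replicate lists, as it did for 190 of 6281 peaks. Whether the local background of a call without control takes up broad signal stays open: relative to the lowest background of its list, it had a median of 1.31 at these peaks and 1.02 at the others, but the peaks were chosen by a fold whose denominator is that background, which builds the difference in. Extra copies of the RGA sequence in the transgenic plants remain possible, since the relative background around RGA was 2.39 ± 0.20 in the RGA-GFP lists (SD, n = 3) and 1.17 and 1.18 in wild type libraries 1 and 3. However, 2 of 3610 other regions of 20 kb reached it with no transgene there that the labels name. The measures were unlike: RGA was scored by the mean over the peaks of its window, each other region by its highest peak in each list. This favours the other regions, so their count cannot decide the question. Copies and broad binding of RGA to its own gene cannot be told apart.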

How the results depend on the processing

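The number of peaks kept its direction and the smallest p its test can give in all alternatives, from 7.63 times (relative to tags kept) and 8.79 times (fold of at least 3) to 25.5 times (without wild type replicate 1; 13.8 without replicate 2). With the replicate number as a block the ratio was 17.4 and the exact p 0.25, the smallest 3 pairs can give; the libraries share only a number, with a product of same-number deviations of −0.0566. Shares of overlap depended on how overlap was defined. Pooled peaks found in all RGA-GFP replicates were 73.2% with 50% of the length required, 52.8% with summits within 100 bp, 97.9% at a −log10 q of at least 10, and 78.8% to 85.2% with a replicate left out. The mean share found in each replicate was 73.3% with summits within 100 bp and 98.8% at the stricter q. Peaks shared between replicates were 65.5% with 50% both ways, 50.2% with summits within 100 bp, and 80.2% to 84.3% with a replicate left out. Overlap with wild type was 3.83% with 50% of the length, 11.6% at the stricter q and 2.02% to 6.21% with a wild type replicate left out, lowest without replicate 1. Summits beside a gene were 27.8% within 500 bp, 48.5% within 3000 bp, 43.8% at the stricter q and 39.99% among peaks in all RGA-GFP lists and no wild type list; those inside a gene were 34.1% and 44.8% under these last settings. Stricter settings admit fewer peaks by construction; for the higher share beside genes and the higher overlap with wild type at the stricter q, the cause was not tested.

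Genes with a pooled peak fell to 2397, all among the 8156, at a −log10 q of at least 10, and to 3501 (3270 of them among the 8156) with the summit in the gene, a rule chosen after seeing the data. Passing lists numbered 9 at the stricter q, 9 with peaks in all RGA-GFP lists and no wild type list, and 6 with the summit in the gene, with fewer genes counted in each. The 2000 strongest peaks are the peaks of the stricter q, and gave the same 2397 and 9. Jasmonate genes turned to below other genes at the stricter q (7.69%, Fisher adjusted p = 1), without pooled peaks that overlap wild type (15.4%, adjusted p = 0.474, chosen after seeing the data) and in all RGA-GFP lists with no wild type peak (15.4%, adjusted p = 0.769), and clock genes with the summit in the gene (10%, adjusted p = 1); the cause was not tested. Lists that never passed also turned: anther markers to below other genes when listed with 3 replicates (22.2%), with summits within 1000 bp (11.1%) and in the gene (0%), seed storage genes to below them at the stricter q (0%), when listed with 3 replicates (30% against 30.1%), within 1000 bp (20%) and in the gene (10%), and root markers to above them at the stricter q (11.1%). Over 12 alternatives for each of 22 lists, 212 of 264 kept direction and side of the threshold, 37 kept direction but lost the call, 15 turned and none gained a call. Calls were lost without turning under 9 alternatives for shoot meristem genes, 8 for DELLA partners, 5 for brassinosteroid and for clock genes, 3 for floral and for cytokinin genes, 2 for jasmonate genes, and 1 for INDETERMINATE DOMAIN and for polarity genes. The calls of DELLA, gibberellin perception, cell cycle inhibitor, auxin, TCP and SPL, and photosynthesis lists held in all 12; those of DELLA partners and shoot meristem genes ended without RGA-GFP replicate 1 (55.6% and 43.8%) or 2 (the same shares), a setting that also requires each pooled peak in both other replicates, so the loss cannot be put down to the replicate alone. Also chosen after seeing the data were peaks relative to tags kept, overlap recomputed from the peak list, genes listed with 3 replicates, and summits within 1000 bp of a gene. Windows of 3000 bp upstream to 1000 bp downstream or of 1000 bp upstream alone, and the motif alternatives, were not run. Depth, lowest at 3999159 tags in wild type library 3, limits how weak a background peak can be seen.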

Other observations

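The tests of this part were not fixed in advance: the gene classes, the stretches and the genes without a pooled peak were looked at after the data had been seen. The authors' deposited table lists 1259 genes (14.4% of 8772) with all 3 replicate lists but with a pooled fold of 0. Among floral genes these were AG and PI, of 13 members with 3 replicate lists. Among cytokinin genes they were the response regulators ARR6 and ARR15, of 14 such members. The polarity gene FIL (of 11 such members), TCP8 (of 12) and the root hair gene COBL9 (of 2) were the others in the preset lists. No list was tested for an excess of such genes. Peaks that all 3 RGA-GFP replicates shared but the pooled list lacked made up 18.84%, 18.84% and 19.02% of the shared peaks of replicates 1, 2 and 3. Of these, 23.2%, 22.6% and 22.5% overlapped a wild type peak, against 8.45%, 8.44% and 8.35% of the shared peaks with a pooled peak.

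Classes of genes beyond the protein-coding ones differed in how often an RGA-GFP peak lay within 200 bp. Of 3480 long noncoding RNA genes, 22.2% ± 2.18 (SD, n = 3 lists) had one, against 12.5% after shuffling, a ratio of 1.78, while wild type peaks gave 1.59 times their shuffled share. MicroRNA genes stood close to the shuffled level, at 10.8% ± 0.354 of 326 genes against 9.86%, a ratio of 1.1, and wild type peaks lay at 2, 4 and 5 of them, 2.12 times their shuffled share. Pseudogenes stood below it, at 3.40% ± 0.128 of 3917 against 23.3%, a ratio of 0.146 (0.551 in wild type). Shuffled peaks were placed over whole chromosomes, whether or not reads could be placed there. A low or high ratio can therefore also come from where the genes of a class lie. Protein-coding genes were at 31.3% ± 2.38 (SD, n = 3) against 23.6%, a ratio of 1.33 (0.838 in wild type).

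Broad stretches like that at RGA lay elsewhere too, and 2 of these places are named here after their values were seen. On chromosome 1, a peak of 7808 bp over AT1G27565 and AT1G27570 (9574677 to 9582484) had a pooled fold of 3.03 against a mean of 1.92 in the replicate lists, and a neighbouring one (9568761 to 9571609) 2.88 against 2.00. On chromosome 5, a peak over AT5G46770 and AT5G46780 (18977290 to 18980094) had 2.67 against 1.87, and the peak at MYC3 (18974119 to 18976958), a gene of jasmonate-responsive transcription, 2.49 against 1.86.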
